A study of Mus musculus with 8 samples.

How the data were processed

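Chromatin accessibility was measured in 8 libraries from mouse embryoid bodies at day 4 of differentiation. Per the labels' protocols, 50000 sorted live cells per library went through the Omni-ATAC procedure, an ATAC protocol in which the Tn5 transposase cuts open chromatin and adds sequencing adapters in 1 step, and the libraries were sequenced as paired ends of 75 bp. The labels give 4 groups of 2 libraries. WT DP and WT SP are PDGFRalpha+FLK1+ and PDGFRalpha-FLK1+ cells of the A2lox.Cre embryonic stem cell line. KO DP is PDGFRalpha+FLK1+ cells of an Etv2 knockout line. OE SP is PDGFRalpha-FLK1+ cells of the iETV2 line, in which Etv2 was induced with doxycycline at 2 µg/ml from day 2.5. The stem cell line goes with genotype and with doxycycline, so an effect of Etv2 and a difference between lines cannot be told apart in the KO and OE comparisons. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

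The deposited table holds 168842 regions with 1 value per library. Per the submitters' processing notes, Bowtie2, MACS2 and DiffBind 3.14.1 were used with the mouse build mm10, without a statement of what each did. The name of the deposited file, not a stated method, calls its values normalized counts, and they are treated as a signal, that is, normalized reads in each region. Region width ran from 401 to 1126 bp with a median of 401 bp. In each library 100% of the values were whole multiples of a library-specific step at a tolerance of 0.01 reads, so whole reads could be recovered. How the scaling factors were set, whether reads were shifted for the Tn5 cut, how duplicates and mitochondrial reads were treated, and whether peaks were called per library or on pooled reads are not given in the sources used here. A scaling factor that follows the reads in peaks, or one that follows the whole library, moves the balance of rises and falls but not the order of the regions, and results are therefore given under other scalings where these differ.

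Recovered reads in regions were 16575336 and 17762310 for WT DP, 17380195 and 17371235 for WT SP, 18853733 and 12477601 for KO DP and 18818425 and 13124581 for OE SP. The median region held 27.0 to 42.0 reads per library, so a change of 2-fold in a median region is near the limit of what 2 libraries per group can show. Reads without molecular identifiers are not independent molecules, so floors and counting intervals cover counting error only. Where a group had 0 reads in both libraries, a floor of 3 reads over the group was used. Between replicates, the chi-square per degree of freedom of the recovered reads was 1.15 for WT DP, 1.21 for WT SP, 1.22 for KO DP and 4.40 for OE SP, and the correlation of log2 values across regions was 0.978, 0.978, 0.975 and 0.937. No 2 libraries agreed within sampling noise, and all 8 were used as separate samples. The deposited factors differed from median-of-ratios factors by 0.23 and 0.05 on the log2 scale in OE SP, -0.11 and -0.11 in WT SP, 0.02 and 0.10 in KO DP, and -0.02 and -0.00 in WT DP.

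The comparisons, tests, gene lists, the rule for named regions and most alternatives were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 5) for the 167573 regions (99.2%) with a mean of at least 10 over the 8 libraries, with 1 fit of 4 group means, an empirical Bayes trend, 4 residual degrees of freedom and a prior of 8.15. A region was called at a Benjamini-Hochberg adjusted p below 0.05 over all regions tested, and all log2 changes are on the log2(value + 5) scale, which understates changes of low regions. All p-values are two-sided. The comparisons were WT SP with WT DP, KO DP with WT DP and OE SP with WT SP. The named regions are those at Etv2, Kdr and Pdgfra, the 5 largest called rises and falls whose groups do not overlap, and in each gene list up to 4 genes by their region of lowest adjusted p.

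Regions were assigned to genes with a gene table of the mm10 assembly that gives gene spans without strand or sequence. The plan named the nearest transcription start within 100 kb. In its place the nearest protein-coding gene span within 100 kb was used, and a region within 1 kb of either end of a gene is called a gene-end region. This gave a gene to 150722 regions (89.3%) and regions to 18519 of 21883 genes. Of the 10000 regions with the highest mean, 65.05% lay within 1 kb of a gene end, against 5.17% after a shift of 1 Mb, which fits the table to the build of the regions. Gene lists (endothelial, hematopoietic, cardiac, paraxial and streak mesoderm, smooth muscle and mesenchyme, pluripotency, endoderm, neuroectoderm and housekeeping) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 9 lists of a comparison. All genes of the lists were in the gene table, and 1 smooth muscle gene, 1 endoderm gene and 3 housekeeping genes had no region. Sox7 and Gata4 are in the endoderm list as well as in the endothelial and cardiac lists. Motif tests and corrections for GC content need the genome sequence and were not run.

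Alternatives were pseudocounts of 1 and 20, no filter and a mean of at least 50, median-of-ratios rescaling over all regions and over the 10000 highest, quantile normalization, a fit of the compared groups alone, a robust fit, a replicate block, removal of chromosome medians, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Added after the data were seen were removal of the median of each 5 Mb window, a fit without the shifted segments, assignment to the nearest gene end, and list counts under the other scalings. Where a library was left out, the remaining library of its group was assumed to vary like the other groups. For comparisons that share control libraries, 20 simulations of unchanged groups gave the correlation and covariance that the shared libraries alone produce. Python 3.11.15 with scipy 1.17.1 was used for the remaining tests.

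The fits were tested on simulated reads with 50 regions changed at each fold. With dispersions on the fitted trend, limma recovered 38% of 2-fold and 82% of 4-fold changes for WT SP with WT DP, 36% and 90% for KO DP with WT DP, and 38% and 84% for OE SP with WT SP, and 2.91%, 4.59% and 6.54% of its calls were false. With a separate dispersion estimated for each region, the false share was 17.3%, 26.4% and 19.6%, above the nominal 5%. The counts of called regions can thus hold more false calls than their adjusted p states. On the same simulation for KO DP with WT DP, 26.9% of edgeR calls and 15.1% of DESeq2 calls were false. In all these simulations a region had the same dispersion in every group, and few regions were changed. The wider spread of the OE SP replicates and the many calls in OE SP were thus left out. The simulated rates therefore do not carry over to OE SP with WT SP.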

Results

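Accessible chromatin was profiled in sorted cells of mouse embryoid bodies, aggregates of differentiating embryonic stem cells, at day 4. The sort used FLK1, the VEGF receptor encoded by Kdr that marks mesoderm with vessel and blood potential, and PDGFRalpha, a receptor of paraxial and cardiac mesoderm encoded by Pdgfra. Cells with both receptors (DP) and with FLK1 alone (SP) were taken from the wild-type A2lox.Cre line, DP cells from an Etv2 knockout (KO) line and SP cells from a line with doxycycline-induced Etv2 (OE), with 2 libraries per group. Etv2 is an ETS transcription factor required for endothelial and blood development, and the series concerns what progenitors marked by Etv2 or Flk1 give to vessels, blood and heart. Each library held 12477601 to 18853733 reads in 168842 regions of build mm10. The first principal component took 71.0% of the variance and the second 13.1%. On the first component the OE SP libraries lay at 367 and 363, the WT SP libraries at -23.9 and -32.2, the WT DP libraries at -159 and -163 and the KO DP libraries at -179 and -174.

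Etv2, on chromosome 7 from 30633616 to 30636509, carried 3 regions. The region at 30634628 to 30635028 inside the gene measured 563 and 611 normalized reads in the WT DP libraries, 475 and 493 in WT SP, 425 and 645 in OE SP, and 0.840 and 0 in KO DP. The region at 30633790 to 30634190 measured 124 and 98.8 in WT DP, 94.7 and 89.2 in WT SP, 75.9 and 63.1 in OE SP, and 0 in each KO DP library. The region at the other end of the gene, 30636355 to 30636755, measured 133 and 109.6 in WT DP, 145 and 148 in WT SP, 159 and 290.4 in OE SP, and 199.8 and 193 in KO DP. The labels' genotype of the knockout thus went with missing reads over 2 of the 3 regions. The region inside the gene had 1 read over both KO DP libraries against 1260 in WT DP, a ratio of 1195 with a 95% counting interval of 214 to 47226 (log2 change -6.77, SE 0.21, adjusted p = 3.24e-08). The region at 30633790 had 0 reads against 238 and was at least 75.2-fold lower in KO DP, with a floor of 3 reads over the group (adjusted p = 1.02e-06). Which part of the gene was altered is not given in the sources used here. No Etv2 region was called between WT SP and WT DP (adjusted p = 0.395 to 0.487) or between OE SP and WT SP (adjusted p = 0.0809 to 0.680), and accessibility at the gene does not give the amount of induced Etv2. The region at 30636355 was called higher in OE SP after median-of-ratios rescaling (log2 change 0.78, adjusted p = 0.00730) and without OE SP replicate 1 (0.97, adjusted p = 6.32e-08). The other scalings, edgeR and DESeq2 called it there too. It was also called higher in KO DP under quantile normalization (0.77, adjusted p = 0.0198), rescaling on the 10000 highest regions, edgeR and a fit of the compared groups alone. The region at 30634628 was called lower in WT SP than in WT DP under quantile normalization (-0.49, adjusted p = 0.0413), rescaling on the 10000 highest regions and a fit of the compared groups alone. It was called higher in OE SP with edgeR (0.37, adjusted p = 0.0488) and without OE SP replicate 1 (0.41, adjusted p = 0.0242).

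**Figure D1:**
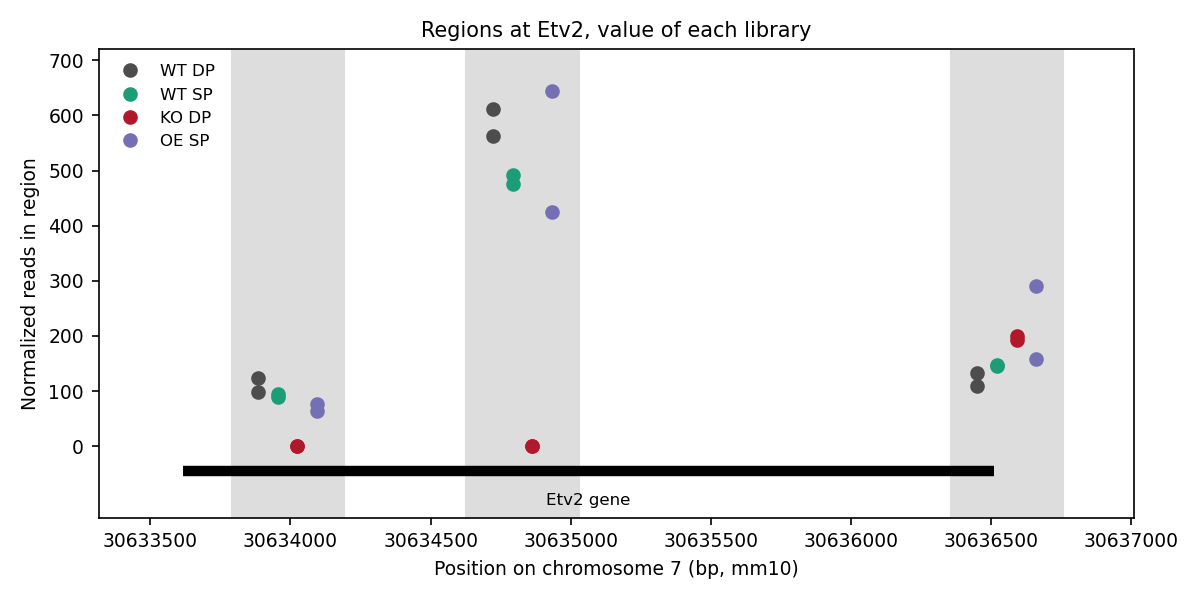
Normalized reads (vertical axis) of the 8 libraries in the 3 regions at Etv2 against position on chromosome 7 (horizontal axis, bp), with a point for each library, shifted sideways by group, grey bands for the regions and a bar for the gene. KO DP lies at 0 or 0.840 in the regions starting at 30633790 and 30634628, and at 199.8 and 193 in the region starting at 30636355.

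The comparison of WT SP with WT DP asks how the FLK1+ mesoderm without PDGFRalpha differs from that with it. Some regions near endothelial and blood genes were higher in WT SP, while most regions of these genes were not called. A region in Flt1, which encodes a VEGF receptor, measured 193 ± 10.7 normalized reads in WT SP against 30.0 ± 5.61 in WT DP (mean ± SD, n = 2; log2 change 2.51, SE 0.21, adjusted p = 0.000146). A region in Ets1, an ETS factor of endothelial cells, rose by a log2 change of 2.61. Both genes also had falls, with 3 rises and 3 falls among 42 regions of Flt1 and 6 and 3 among 41 of Ets1. A region in Vav1, a signalling protein of blood cells, measured 101 ± 28.9 against 9.27 ± 2.13 (2.87). Among blood genes, regions at Itga2b (CD41, an early blood marker; 2.29), near Ptprc (CD45; 1.52) and in Ikzf1 (2.03) also rose. Of the 8 regions of Tal1, a master regulator of blood formation, 6 rose and none fell. Some regions of early mesoderm genes fell, among them a region at Mesp2 from 807 ± 31.1 in WT DP to 282 ± 2.56 in WT SP and a region near Foxc1 from 503 ± 14.6 to 153 ± 12.1 (-1.68).

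In the endothelial list, 79 of 557 regions rose and 36 fell, 89 and 36 adjusted over the list alone, and its median lay 0.13 above that of all regions (camera adjusted p = 0.0167, adjusted p = 0.868 with an estimated correlation). Of its 34 genes, 11 had rises only, 1 had falls only and 12 had both. A region near Nrp1 (-2.05), a co-receptor for VEGF, was among the falls. In the hematopoietic list, 48 of 364 regions rose and 18 fell, 51 and 18 adjusted over the list alone, with a median 0.16 above all regions (adjusted p = 0.00668, adjusted p = 0.868 with an estimated correlation). In the paraxial and streak mesoderm list, 11 of 374 regions rose and 68 fell, 13 and 69 adjusted over the list alone, with a median -0.24 from all regions (adjusted p = 0.000370, adjusted p = 0.803 with an estimated correlation). Its falls included regions at Tbx6 (655 ± 20.8 to 229 ± 7.10), which specifies paraxial mesoderm, and near Snai1 (-1.67), which drives the epithelial to mesenchymal transition. The housekeeping list moved as well, with 11 of 115 regions up and 2 down, 8 and 1 adjusted over the list alone. Its median lay 0.13 above all regions (adjusted p = 0.0167, adjusted p = 0.868 with an estimated correlation, and 0.0505 without WT SP replicate 1). Its called regions included those near Tfrc (-1.49), Ywhaz (2.11), Eef1a1 (1.04) and Polr2a (1.06). The last was lost on leaving out any library of the comparison and that near Eef1a1 on leaving out WT DP replicate 1, WT DP replicate 2 or WT SP replicate 1.

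In the cardiac list, 34 of 537 regions rose and 30 fell, 31 and 28 adjusted over the list alone (adjusted p = 0.323). A region at Myl7, an atrial myosin light chain, fell from 249 ± 4.81 to 55.2 ± 3.23 (-2.08) and regions near Mesp1 (-1.20), the factor of early cardiac mesoderm, and Wnt5a (-1.52) fell, while a region near Fgf10 rose (2.83). The remaining lists were not called. In the smooth muscle and mesenchyme list 21 of 256 regions rose and 13 fell, 20 and 13 adjusted over the list alone (adjusted p = 0.323). Called regions included falls in Myh11 (-1.47) and Zeb2 (-1.82) and rises near Acta2 (1.16) and Thy1 (1.58). In the pluripotency list 14 of 211 rose and 13 fell, with 14 and 13 adjusted over the list alone (adjusted p = 0.901). Its median lay 0.01 below that of all regions while camera gave an upward direction. Its called regions included those near Dppa4 (3.42), Tet1 (1.41), Klf5 (1.18) and Prdm14 (-1.01). The last was lost without WT DP replicate 2 or WT SP replicate 1 and that near Klf5 without WT DP replicate 1. In the endoderm list 27 of 256 rose and 20 fell, 28 and 21 adjusted over the list alone (adjusted p = 0.835). Regions in Lama1 (-3.25) and near Cxcr4 (-1.75) fell. Regions in Cubn (2.26) and near Sox7 (1.89), which is in the endothelial list too, rose. In the neuroectoderm list 9 of 258 rose and 25 fell, 8 and 25 adjusted over the list alone, with a median -0.15 from all regions (adjusted p = 0.0575). It passed after median-of-ratios rescaling (-0.15, adjusted p = 0.0236) and quantile normalization (-0.14, adjusted p = 0.0291), while the deposited values gave adjusted p = 0.868 with an estimated correlation. Over its alternatives at the preset correlation the adjusted p ran from 0.0236 to 0.178. Regions in Ncam1 (-2.27) and Msi1 (-1.36) and near Sox1 (-1.11) were among its falls, the last lost without WT DP replicate 1 or WT SP replicate 2. After rescaling on the 10000 highest regions, falls outnumbered rises in the cardiac (19 rises and 59 falls), smooth muscle (10 and 25), pluripotency (10 and 24) and endoderm (21 and 37) lists, and the housekeeping list had 7 rises and 6 falls.

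By size, the largest rises lay near Ap1m1 on chromosome 8 at 72268316 to 72268716 (269 ± 7.86 in WT SP against 20.4 ± 5.48, log2 change 3.45), near Dppa4, near Cyp4a10 (3.33) and in Mrtfb (3.20). The largest falls lay in Lama1 on chromosome 17 at 67728828 to 67729228 (12.1 ± 0.225 against 158 ± 17.2), in Tmprss11f, in Tenm2 (-2.95), and at sites with no gene within 100 kb on chromosome 8 at 90555246 (-3.17) and chromosome 7 at 40218934 (-3.03). At the sort markers, 8 of 43 regions of Kdr rose and 4 fell, and 2 of 28 regions of Pdgfra rose and 4 fell. These follow from the sort or cannot be separated from it, and include a rise of 3.42 and a fall of -2.30 inside Kdr.

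Over all 167573 regions tested with limma, 10395 rose and 13600 fell in WT SP, and 6652 and 9190 did so by at least 2-fold. The split depended on scaling and on the fit. Rises were 43.3% of calls as deposited and 59.1% with the compared groups alone in the fit (37453 rose and 25969 fell). They were 33.1% with DESeq2 and 23.2% after rescaling on the 10000 highest regions (6720 rose and 22303 fell). That last rescaling moved the median of all regions from 0.11 to -0.11 and left the endothelial list with 55 rises and 54 falls and the hematopoietic list with 35 and 33. Without WT DP replicate 1, WT DP replicate 2, WT SP replicate 1 or WT SP replicate 2, the rises numbered 2316, 2228, 1784 and 2027 and the falls 3988, 3503, 4168 and 5034.

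**Figure D2:**
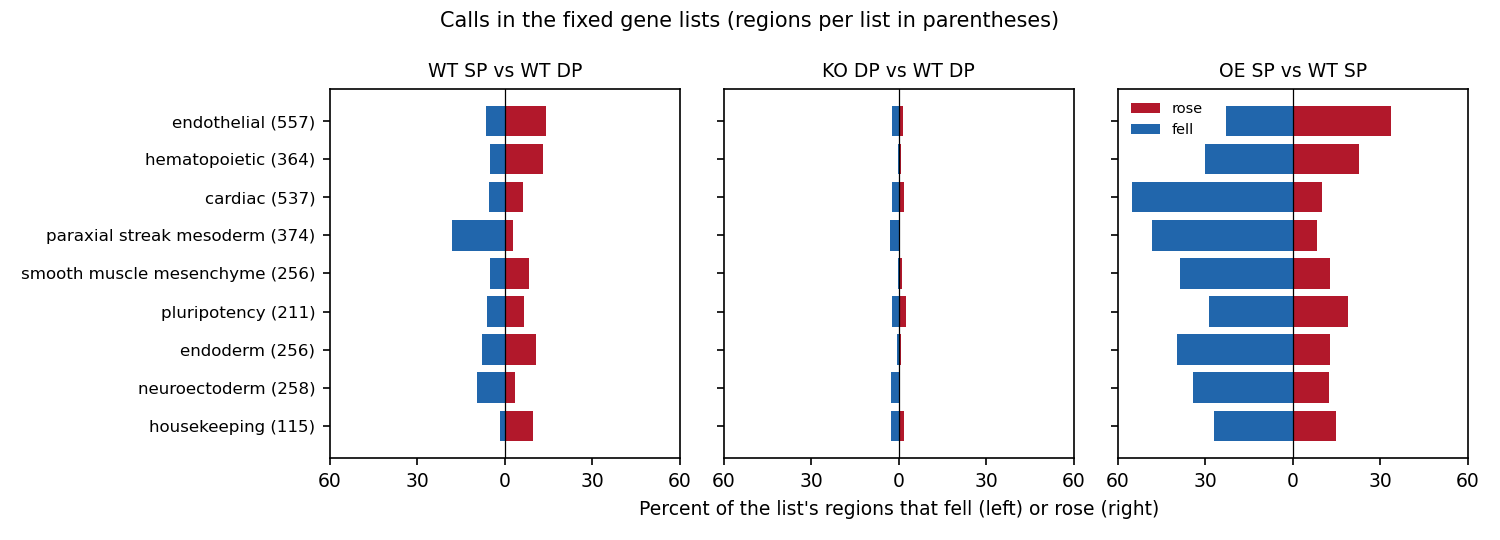
Percent of each list's regions that rose (right, red) or fell (left, blue) in the 3 comparisons under the deposited scaling, with the number of regions of each list in parentheses. The paraxial and streak mesoderm list has 18.2% falls in WT SP against WT DP, and the cardiac list has 55.3% falls in OE SP against WT SP. The balance turns to more rises than falls in OE SP for the hematopoietic, pluripotency and housekeeping lists after median-of-ratios rescaling.

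The comparison of KO DP with WT DP asks what differs in PDGFRalpha+FLK1+ cells when Etv2 is lost. Few regions of the lineage lists changed, and few of all regions did (1.72% rose and 2.21% fell). The shares were near these in the endothelial list (1.26% and 2.33%) and the cardiac list (1.68% and 2.23%). They were lower in the hematopoietic list (0.82% and 0.27%). A region in Tek, the endothelial receptor TIE2, on chromosome 4 at 94765177 to 94765577 fell from 46.6 ± 1.40 in WT DP to 5.32 ± 0.794 in KO DP (log2 change -2.32, SE 0.21, adjusted p = 8.05e-05), inside a block of chromosome 4 whose median was lower. A region near Hand1, a factor of the early heart fields, fell from 266 ± 23.2 to 51.5 ± 9.03 (-2.27), and a region in Ldb3, a sarcomere protein, fell as well (-1.96). A region near Isl1, a factor of second heart field progenitors, rose from 29.5 ± 2.28 to 166 ± 20.9 (2.31). So did a region in Flt1 from 12.6 ± 1.35 to 69.8 ± 7.23 (2.08) and a region near Klf4, a pluripotency factor, from 35.0 ± 0.059 to 159 ± 3.66 (2.04). Isl1, Flt1 and Klf4 each also had 1 region that fell, and Ldb3 had 4 falls and 1 rise.

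No list was called. In the endothelial list 7 of 557 regions rose and 13 fell, with the same 7 and 13 adjusted over the list alone (adjusted p = 0.676). Of its 34 genes, 22 had no called region. Beside Tek and Flt1, its called regions included that near Nrp1 (2.02), lost without KO DP replicate 2. A region near Cdh5, VE-cadherin, fell from 108 ± 2.67 to 45.3 ± 0.126 (-1.17), in a stretch of chromosome 8 whose windows lay lower, and was lost on leaving out any library of the comparison. In the hematopoietic list 3 of 364 rose and 1 fell, 1 and 0 adjusted over the list alone (adjusted p = 0.837), with a rise near Meis1 (1.31) and a fall in Zfpm1 (-0.65). In the cardiac list 9 of 537 rose and 12 fell, 9 and 12 adjusted over the list alone (adjusted p = 0.771), with a rise in Tnni1 (1.67). Its median lay 0.06 above that of all regions while its mean was -0.02. In the paraxial and streak mesoderm list 2 of 374 rose and 11 fell, 2 and 6 adjusted over the list alone (adjusted p = 0.389). Called regions included falls at Aldh1a2 (-0.91), the retinoic acid enzyme, in Wnt3 (-0.91) and at Msgn1 (-1.02), and a rise near Lhx1 (1.19). In the neuroectoderm list 0 of 258 rose and 7 fell, 0 and 6 adjusted over the list alone (adjusted p = 0.255, and 0.0430 with regions within 10 kb of a gene, where the median was -0.13 from all regions). With an estimated correlation the whole list had adjusted p = 0.962. Regions near Sox1 (-1.64), Zic1 (-1.04) and Hes5 (-0.84) and in Lhx2 (-0.84) fell. After rescaling on the 10000 highest regions the balance turned to 18 rises and 16 falls for the endothelial list, 22 and 11 for the cardiac list and 7 and 6 for the neuroectoderm list. It gave 9 and 10 for the paraxial and streak list, 10 and 4 for the housekeeping list, 13 and 4 for the pluripotency list and 12 and 2 for the endoderm list.

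The smooth muscle and mesenchyme list had 3 rises and 1 fall of 256 regions, 0 and 0 adjusted over the list alone (adjusted p = 0.389). These lay at Tagln (0.78), near Col1a2 (1.12), in Myh11 (1.08) and in Twist2 (-1.21). The pluripotency list had 5 and 5 of 211, 8 and 5 adjusted over the list alone (adjusted p = 0.837), with a rise near Klf2 (1.60) and falls near Esrrb (-1.28) and Klf5 (-1.19). Its median lay 0.02 below that of all regions while camera gave an upward direction. The endoderm list had 2 and 2 of 256, 0 and 0 adjusted over the list alone (adjusted p = 0.389), with falls near Cxcr4 (-0.93) and in Amn (-0.81). The housekeeping list had 2 and 3 of 115, 4 and 3 adjusted over the list alone (adjusted p = 0.389), with Hprt and a region near Polr2a (1.10) up and a region near Ywhaz down (-1.26). Of the 40 named regions called here outside Kdr and Pdgfra, 16 kept their call under every alternative. Those are the regions of Etv2, Tek, Flt1, Isl1, Hand1, Ldb3, Klf4 and Hprt and the other regions of largest change. The remaining 24 lost it on leaving out at least 1 library. Of these, 22 were lost without WT DP replicate 1, 22 without WT DP replicate 2, 20 without KO DP replicate 1 and 24 without KO DP replicate 2. At the sort markers, 2 of 43 regions of Kdr and 0 of 28 of Pdgfra rose, and none fell.

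The changes of largest size lay at sites with many reads in 1 line and few or none in the other. Beside Etv2, a region at an end of Hprt, the purine salvage gene, on chromosome X at 52987879 to 52988279 had 678 reads in KO DP and 0 in WT DP, at least 238-fold higher with a floor of 3 reads over the group. A region near Cndp2 on chromosome 18 at 84660684 was of the same kind (749 reads against 0, at least 263-fold). A region near Gm33989 on chromosome 7 at 39655244 had 0 reads in KO DP against 613 (at least 194-fold lower). Regions at 5730507C01Rik (722 ± 79.8 in KO DP against 5.50 ± 3.66) and near LOC115488002 (765 ± 62.2 against 8.90 ± 1.15) on chromosome 12 also rose. A region in Gas2 on chromosome 7 fell (6.99 ± 3.17 against 945 ± 16.2).

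Some changes covered whole blocks. On chromosome 4 from 85 to 105 Mb, the median of 1358 regions in KO DP lay -0.53 from that of all regions, with 275 falls and 5 rises. As a median minus that of all regions, the same block lay at -0.10 in WT SP against WT DP and 0.07 in OE SP against WT SP. By library, with each library's own median removed, the KO DP libraries lay at -0.56 and -0.56 against the mean of WT DP. On that measure the WT SP libraries lay at 0.05 and 0.02 and the OE SP libraries at 0.07 and -0.09. Over the 9605 regions of chromosome 8 the median lay at 0.20 in KO DP, with 451 rises and 235 falls. That shift was uneven along the chromosome. The part from 50 to 70 Mb lay at 0.35 with 49 rises and 1 fall, while the windows around Cdh5 lay lower. The 40 regions of chromosome Y lay at 0.62, with 18 rises and 7 falls. These bounds were set after the window medians had been seen.

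**Figure D3:**
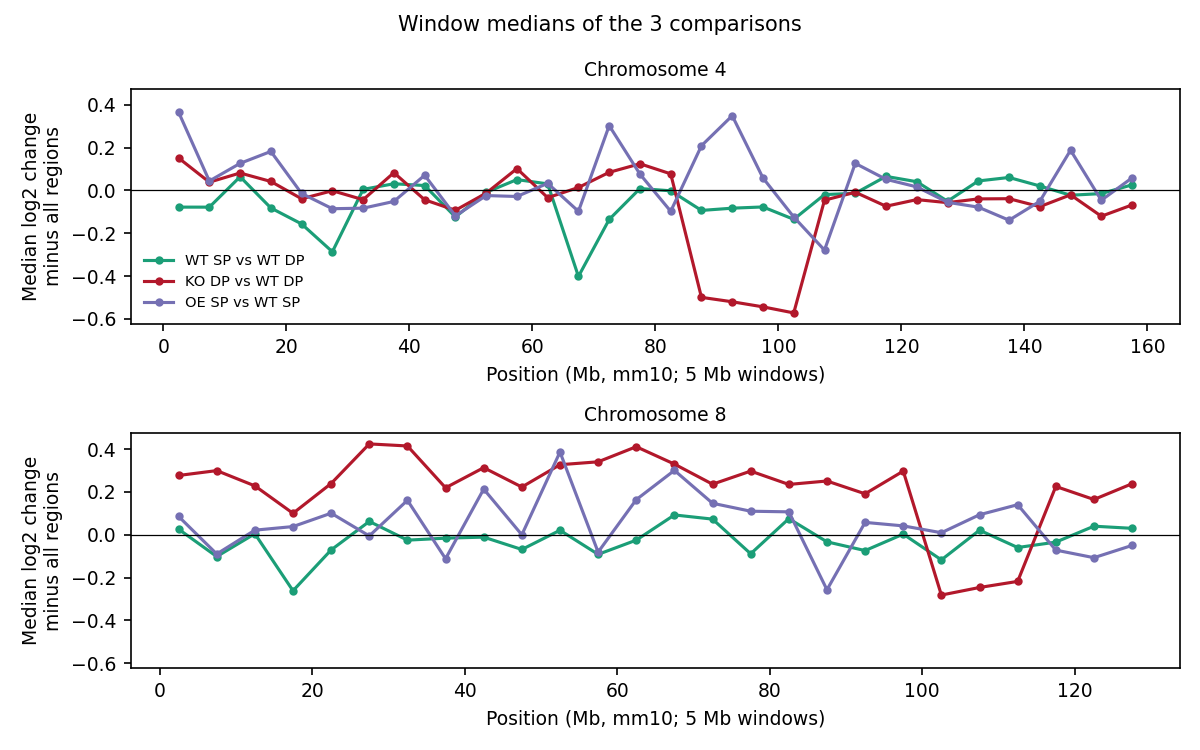
Median log2 change of the regions in each 5 Mb window of chromosomes 4 and 8, minus the median of all regions (vertical axis), against position in Mb (horizontal axis), with a line for each comparison. In KO DP against WT DP, the windows from 85 to 105 Mb of chromosome 4 lie together below 0, with a median of -0.53 over their 1358 regions.

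Over all 167573 regions, limma called 2881 higher and 3696 lower in KO DP, 2440 and 2397 of them by at least 2-fold. Rises were 43.8% of calls as deposited, 61.2% after rescaling on the 10000 highest regions (6160 rose and 3902 fell), 56.5% with edgeR (6061 and 4661) and 59.9% with DESeq2 (2054 and 1373). Without WT DP replicate 1, WT DP replicate 2, KO DP replicate 1 or KO DP replicate 2, the rises numbered 649, 646, 523 and 473 and the falls 444, 433, 617 and 420.

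The comparison of OE SP with WT SP asks what induced Etv2 changes in PDGFRalpha-FLK1+ cells. Some regions near endothelial genes rose and others fell, and among called regions of cardiac and early mesoderm genes falls outnumbered rises. Falls outnumbered rises over all regions too, where 31.9% fell and 16.6% rose as deposited. In the cardiac list 55.3% fell and 10.1% rose, and in the paraxial and streak list 48.4% and 8.29%. The shifts of the endothelial, cardiac and paraxial and streak lists were not called with an estimated correlation (adjusted p = 0.931 for each). A region near Cldn5, the endothelial tight junction protein, measured 594 ± 87.0 in OE SP against 61.8 ± 1.86 in WT SP (log2 change 3.16, SE 0.22, adjusted p = 3.73e-06). A region in Flt4, the lymphatic VEGF receptor, measured 560 ± 49.5 against 87.3 ± 4.05 (2.61). A region near Fli1, an ETS factor of endothelium and blood, measured 920 ± 264 against 68.3 ± 1.57 (3.63). Among heart genes, a region in Ryr2, the cardiac calcium release channel, fell from 115 ± 14.9 to 7.66 ± 1.54 (-3.25), and regions near Myocd (-2.94), Gata5 (-2.82) and Tbx5 (-3.20), regulators of heart development, fell with it. Among early mesoderm genes, regions in Wnt3 (-3.02) and near Fgf8 (-2.58), Foxc1 (-2.44) and Gsc (-2.61) fell.

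In the endothelial list, 188 of 557 regions rose and 128 fell, 197 and 133 adjusted over the list alone, with a median 0.38 above all regions (adjusted p = 8.93e-05, adjusted p = 0.931 with an estimated correlation). All 34 genes had a called region, 8 with rises only and 26 with both directions. A region near Ets1 fell from 82.3 ± 9.83 to 5.11 ± 2.07 (-3.12). In the cardiac list, 54 of 537 regions rose and 297 fell, 55 and 307 adjusted over the list alone, with a median -0.48 from all regions (adjusted p = 8.93e-05, adjusted p = 0.931 with an estimated correlation). In the paraxial and streak mesoderm list, 31 of 374 rose and 181 fell, 32 and 185 adjusted over the list alone, with a median -0.32 from all regions (adjusted p = 0.000777, adjusted p = 0.931 with an estimated correlation). The directions of these 3 lists held under the 3 other scalings.

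The hematopoietic list was not called (82 of 364 rose and 110 fell, 83 and 114 adjusted over the list alone, adjusted p = 0.448). Its median lay 0.04 above that of all regions while its mean was -0.11, and its balance turned to 110 rises and 94 falls after median-of-ratios rescaling. Regions near Gata2 (2.76) and in Vav1 (907 ± 295 against 101 ± 28.9, 3.10) rose, and regions in Runx1 (-2.59) and near Bcl11a (-2.79) fell. At Tal1, 6 of 8 regions rose and 1 fell. The smooth muscle and mesenchyme list had 33 rises and 99 falls of 256, 33 and 100 adjusted over the list alone (adjusted p = 0.442), with falls in Mylk (-3.03), Twist2 (-3.48), Pdgfrb (-1.64) and Myh11 (-1.24). The endoderm list had 33 and 102 of 256, 33 and 103 adjusted over the list alone (adjusted p = 0.373), with falls near Cxcr4 (-3.32), Gata4 (-2.40) and Foxa2 (-2.25). The neuroectoderm list had 32 and 88 of 258, 31 and 88 adjusted over the list alone (adjusted p = 0.375), with falls near Sox3 (-2.84), Six3 (-2.47) and Sox1 (-2.53) and in Ncam1 (-2.90). The pluripotency list had 40 and 61 of 211, 40 and 61 adjusted over the list alone (adjusted p = 0.567). Its called regions included rises near Klf2 (3.32), which is also a flow-responsive endothelial factor, and Utf1 (2.13) and falls near Prdm14 (-2.53) and in Tfcp2l1 (-2.10). The housekeeping list had 17 and 31 of 115, 14 and 30 adjusted over the list alone (adjusted p = 0.998), with a rise near Actb (1.61) and falls near Ywhaz (-1.77), Eef1a1 (-2.12) and Tfrc (-1.68). After median-of-ratios rescaling the balance turned to 55 rises and 48 falls for pluripotency and 25 and 22 for housekeeping. As deposited, the medians of these lists lay 0.01 and 0.07 above that of all regions, although their means were -0.09 and -0.21.

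By size, the largest rises lay in Mtbp on chromosome 15 at 55593341 to 55593741 (402 ± 68.9 in OE SP against 9.54 ± 0.532, log2 change 4.80), near LOC108167340 (4.26), in Dnah7b (4.20), and at sites with no gene within 100 kb on chromosome 17 at 9430505 (4.41) and chromosome 16 at 53601688 (4.20). The largest falls lay near Gm6569 (24.4 ± 21.2 against 529 ± 25.5, -4.39), near Blk (-4.26), near Gata5 at 180354841 on chromosome 2 (73.2 ± 76.7 against 966 ± 36.5, -4.11), in Hunk (-3.97) and at 59988308 on chromosome 13 (-4.02). The OE SP replicates stood far apart at several of these. The region near Blk measured 13.1 and 239 in the OE SP libraries, and its call was lost in a robust fit. At the sort markers, 15 of 43 regions of Kdr rose and 17 fell, and 7 of 28 regions of Pdgfra rose and 11 fell.

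Over all 167573 regions, limma called 27777 higher and 53530 lower in OE SP, 19909 and 35320 of them by at least 2-fold. The median of all regions was -0.22 as deposited and -0.00 after median-of-ratios rescaling, and that shift moved rises from 34.2% to 47.9% of calls (39093 rose and 42488 fell). Rises were 47.1% of calls under quantile normalization, 49.9% with edgeR and 48.7% with DESeq2. The OE SP replicates differed more than those of the other groups, with a chi-square per degree of freedom of 4.40 against 1.15 to 1.22.

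**Figure D4:**
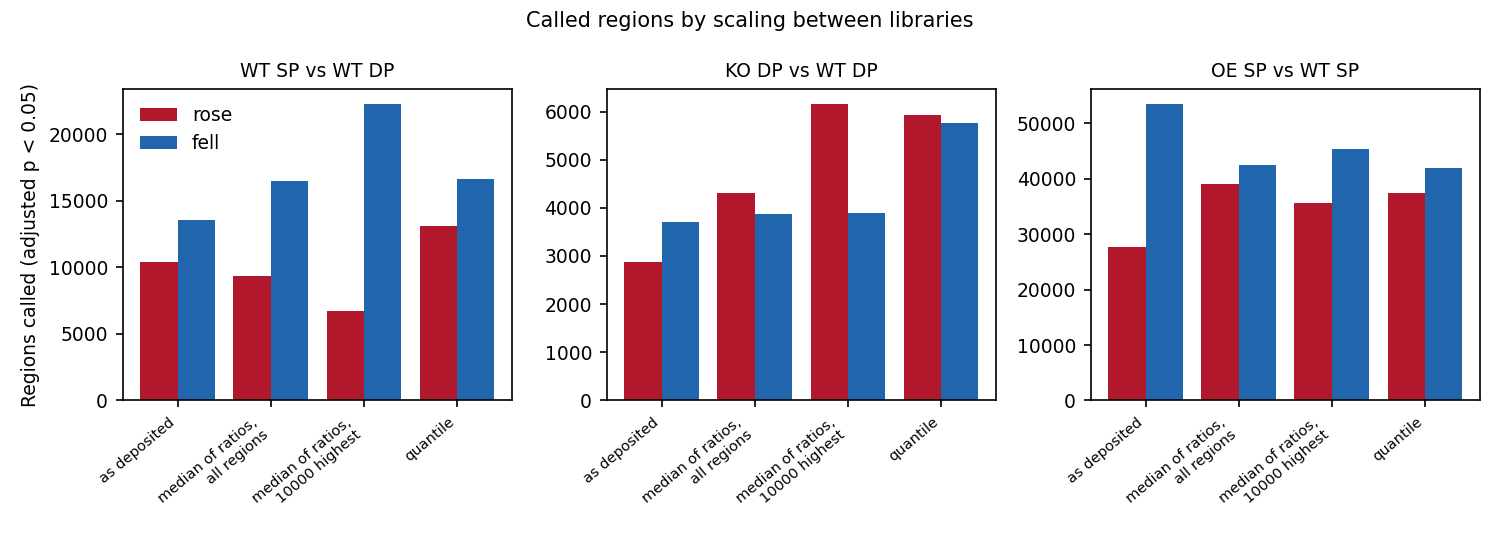
Number of regions called higher (red) and lower (blue) by limma at an adjusted p below 0.05 in the 3 comparisons (vertical axes, each on its own scale), under the deposited scaling and 3 others. In KO DP against WT DP the falls outnumber the rises as deposited (3696 and 2881) and the rises outnumber the falls after median-of-ratios rescaling over all regions (4304 and 3864).

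The KO and OE comparisons share no library, so their changes can be set side by side. Across the 167573 regions the log2 changes had a Pearson correlation of -0.0009 and a Spearman correlation of 0.0024, and regions are not independent replicates. Among called regions, 353 fell in KO DP and rose in OE SP, where independent lists of the same lengths share 613, and 1030 rose in KO DP and fell in OE SP against 920 for independent lists. Falls in both comparisons numbered 1753 against 1181, and rises in both 292 against 478. These counts follow the deposited scaling, under which 34.2% of the OE SP calls are rises.

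The other pairs of comparisons share libraries. The changes of WT SP against WT DP and of KO DP against WT DP, which share WT DP, had a correlation of 0.211 where unchanged groups gave 0.50, and a covariance of 0.0618 where unchanged groups gave 0.0360. Among calls, 438 rose in both against 179 for independent lists and 659 fell in both, more than 2 times the number for independent lists. The changes of WT SP against WT DP and of OE SP against WT SP, in which WT SP enters with opposite signs, had a correlation of 0.178 where unchanged groups gave -0.501, and a covariance of 0.113 where unchanged groups gave -0.0361. Regions that rose in WT SP and again in OE SP numbered 3692 against 1723, those that fell in both 7559 against 4344, those that rose and then fell 3537 against 3321, and those that fell and then rose 464 against 2254. The shared libraries could not be split so that each part kept 2. Part of the excess in the same direction between the WT SP and KO DP changes may therefore come from WT DP, while the shared WT SP works against overlap in the same direction between the WT SP and OE SP changes. Without OE SP replicate 1 the correlation was 0.277, and without OE SP replicate 2 it was 0.0742.

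Called regions lay away from gene ends in most cases. The odds ratio of lying within 1 kb of a gene end, for called regions against the other regions tested, was 0.482 for rises and 0.197 for falls in WT SP. It was 0.481 for rises in KO DP, and 0.342 for rises and 0.522 for falls in OE SP. Falls in KO DP had an odds ratio of 1.18 (95% interval 1.06 to 1.30 by Fisher's exact test), with 12.2% of them at gene ends against 10.6% of other regions. The odds ratio became 0.440 for falls of at least 2-fold. Regions are not independent replicates, so the interval may be too narrow.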

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

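The removal of 5 Mb window medians, the fit without the shifted segments, the assignment to the nearest gene end and the list counts under other scalings were chosen after the data had been seen. The motif tests with their alternatives, the GC correction and the GC correction with the replicate block were not run, for lack of a genome sequence. Regions of Kdr and Pdgfra were followed through the alternatives only where the rule of size or of the gene lists also named them. Over all alternatives, the 137 named region results that were followed gave 2344 values on the same side of the threshold, 122 that lost the call, 15 that gained it and 0 in which a called change turned direction. The Etv2 region at 30634628, not called in OE SP, went from 0.11 to -0.18 without OE SP replicate 2. Named regions were chosen among the largest or clearest changes, which favours stable calls, and in KO DP 16 of 40 named calls were kept under every alternative. Counts of rises and falls in WT SP against WT DP were 4486 and 5467 with a mean of at least 50, where 64553 regions were tested, 6720 and 22303 after rescaling on the 10000 highest regions, and 37453 and 25969 with the compared groups alone in the fit, and the rises were 4663 with DESeq2. In KO DP against WT DP the rises were 1902 with a pseudocount of 1 and 4404 with a pseudocount of 20. Its rises and falls were 750 and 1693 with a mean of at least 50, 5936 and 5769 under quantile normalization, and 14903 and 21995 with the compared groups alone. Its rises were 6160 after rescaling on the 10000 highest regions and 6061 with edgeR, and its falls 1373 with DESeq2. In OE SP against WT SP the rises and falls were 6363 and 24250 with a mean of at least 50, and the falls 28778 with DESeq2. Leaving out 1 library gave 1784 to 2316 rises and 3503 to 5034 falls in WT SP, 473 to 649 and 420 to 617 in KO DP, and 20539 to 34544 and 37651 to 66797 in OE SP. A mean of at least 50 tests fewer regions, and a left-out library leaves a group with 1 sample. In the main fit the 4 groups share 1 spread, although the chi-square per degree of freedom between replicates was 4.40 in OE SP against 1.15 to 1.22 elsewhere. Sharing it tends to raise the p-values of WT SP and KO DP and to lower those of OE SP. With the compared groups alone, calls became more in WT SP and KO DP and fewer in OE SP (23373 rises and 41942 falls). For the remaining settings the cause was not tested. No other alternative, the window, segment and chromosome corrections among them, moved a count by more than 1.5 times.

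Gene list calls were lost with an estimated correlation for the endothelial (median 0.13 from all regions, adjusted p = 0.868), hematopoietic (0.16, 0.868), paraxial and streak (-0.24, 0.803) and housekeeping (0.13, 0.868) lists in WT SP, and for the endothelial (0.38), cardiac (-0.48) and paraxial and streak (-0.32) lists in OE SP (adjusted p = 0.931 for each). The housekeeping call was also lost without WT SP replicate 1 (0.10, adjusted p = 0.0505). The neuroectoderm list gained a call in WT SP after median-of-ratios rescaling (-0.15, adjusted p = 0.0236) and quantile normalization (-0.14, adjusted p = 0.0291), and in KO DP with regions within 10 kb of a gene (-0.13, adjusted p = 0.0430). The odds ratio at a gene end of the falls in KO DP turned from 1.18 to 0.440 for falls of at least 2-fold. The cause of these list and position changes was not tested.

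The correlation of the KO and OE changes was -0.0686 with a mean of at least 50 and -0.0269 to 0.0271 without 1 library. That of the WT SP and KO changes was 0.171 with a mean of at least 50, 0.246 over regions called in either comparison, and 0.178 to 0.272 without 1 library. That of the WT SP and OE changes was 0.287 with a mean of at least 50 and 0.0742 to 0.277 without 1 library. The replicate numbers did not pair the libraries, since same-numbered libraries had deviations correlated at -0.0038 to 0.0560. With the replicate block the counts were 10380 and 13246 in WT SP, 2723 and 3105 in KO DP, and 27544 and 52655 in OE SP, and no gene list call changed. Depth limits what a median region of 27.0 to 42.0 reads can show, and the fewest reads were in KO DP replicate 2 (12477601) and OE SP replicate 2 (13124581).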

Other observations

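The gene blocks, the patterns and their bounds were found in the data. Of the tests, those of scaling and of Etv2 loss for the chromosome 4 block, of tandem families for the regions open in KO DP alone, and of imprinting and absent sequence were chosen after the result was seen.

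Some genes with at least 8 assigned regions, inside the gene or within 100 kb of it, had a large share of them called. In WT SP against WT DP, 6 of 12 regions of Frzb, a secreted Wnt antagonist, and 4 of 8 regions of Col5a2, a fibrillar collagen (with 1 that rose), fell, and 7 of 15 regions of Cubn rose with none that fell. In OE SP against WT SP, 14 of 15 regions of Faim2, 8 of 9 of Casq2, the cardiac calsequestrin, and 7 of 8 of Gdnf (with 1 that rose) fell, and 7 of 9 regions of Ifngr1, an interferon gamma receptor chain, and 10 of 15 of Gypc, a red cell membrane glycoprotein (with 3 that fell), rose. In KO DP against WT DP, 11 of 19 regions of Cpne4 rose, and falls took 9 of 9 regions of Cd244a, an immune receptor, 10 of 11 of Itln1, 7 of 9 of H60b, a ligand of the NKG2D receptor, and 22 of 38 of Dnah8. These genes are the top of a ranking by share under the deposited scaling, and no test was run on them as genes.

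The block of chromosome 4 from 85 to 105 Mb was lower in both KO DP libraries. The block was measured against all regions, and a scaling of whole libraries moves both alike. Its median of -0.55 from all regions under quantile normalization, against -0.53 as deposited, is therefore no test of scaling. A lower copy number of the block in the knockout line is a candidate explanation, which predicted like shifts at gene ends and elsewhere. Against the same kinds of region outside the block, the median was -0.61 for 87 gene-end regions and -0.54 for 1271 others. The difference was -0.0685 (95% bootstrap interval -0.153 to 0.0133), which met the prediction but does not show equal shifts. The bootstrap drew regions as if independent, and the log2(value + 5) scale understates changes of low regions. Copy number is therefore not settled by this test. In the 222 regions of the block with a mean of at least 100, the median lay at -0.65. An effect of Etv2 loss on the block cannot be told apart from the line, because genotype and line go together. Of its regions 89.0% lay below the median of all regions, but the block was chosen for its low window medians, so a high share was fixed in advance. Tek and Cdkn2a lie in this block, and 7 of 9 regions of Cdkn2a fell.

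A set of 80 regions had at least 20 reads in each KO DP library and at most 3 in each of the 6 others, 42 of them with 0 reads in all others, and 10 regions were absent in KO DP alone. The OE SP libraries had 12 and 48 such regions, and WT DP and WT SP had 0 and 0. Foreign cells in the KO DP sort would add reads, so they do not by themselves account for the 10 regions absent there. For the 80 regions open in KO DP alone, foreign cells cannot be told apart from a difference of the line. The region at an end of Hprt, unread in the other lines, had 0.512 of the median of the strongest gene-end regions of 15 other housekeeping genes (327 against 637). That ratio was above the bound set for a minor share, but it rests on a single region that is among the strongest of the set. Sequence that differs between the strains or clones behind the lines is a candidate explanation: of 88 regions specific to KO DP apart from Etv2, 25 lay nearest a gene of a tandem family (at least 5 genes of 1 symbol root within 1 Mb), against 2 of 60 specific to OE SP (odds ratio 11.4, 95% interval 2.64 to 103 by Fisher's exact test) and 2.74% of all regions tested. The regions are not independent replicates and may lie together in a family, so the interval may be too narrow. The tandem family rule replaced a first list of families, picked by hand after the KO DP genes had been seen, which gave 34 of 88 against 3 of 60. Copy number, sequence and mapping were not separated and no biological explanation was tested.

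At genes whose imprinting region is methylated on the maternal copy, regions rose in KO DP at 6 of 16 loci, namely Snrpn, Nnat with its neighbour Blcap, Plagl1, Igf2r, Grb10 and Trappc9, and at 0 of 4 loci methylated on the paternal copy, where random sets gave a mean of 0.899, while 5 of 296 regions of the maternal list and 4 of 79 of the paternal list fell. The locus list was written from background knowledge after Snrpn and Nnat had been noticed, which favours a high count. Random sets matched on the number of regions gave a mean of 2.97 loci and a 95th percentile of 6, with a share of 0.0529 at 6 or more, while a count by gene gave 7 of 18 genes against a mean of 3.03 (share 0.0175), so an imprinting difference between the lines cannot be told apart from chance. A shift of copy number over most of a 5 Mb window is argued against, since 16 of the 18 called rises (88.9%) stayed called with window medians removed. Only windows with at least 30 regions were corrected. A gain of a single locus would pass this correction and was not tested. Absent sequence in the other lines is argued against for the 12 rises outside Snrpn, whose median region had 14.5 reads in its lowest library of the other groups. At Snrpn, 2 regions had 0 to 3 reads in the other groups, and absent sequence remains possible there.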
